A study of Arabidopsis thaliana with 6 samples.

How the data were processed

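RNA from root tips of Arabidopsis thaliana was sequenced in 6 samples, 3 labelled wild type and 3 labelled sos2-2. Per the labels' protocols, seedlings were grown on plates, and at 6 days of age were moved to liquid medium with 100 mM NaCl for 12 hours. Total RNA was extracted with TRIzol and libraries were made with an Illumina RNA-seq kit. The labels do not say whether the 3 samples of a group came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

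The deposited table gives TPM, transcript abundance scaled to a fixed total, for 48359 transcript isoforms in the 6 samples. The unit was read from the values, since each sample sums to 1000000. The submitters' processing notes name kallisto 0.46.2, sleuth 0.30.0 and the build TAIR10, with no role or order. The annotation release, the filters and the strand setting are not given in the sources used here. TPM keeps no trace of sequencing depth, so the depth of each sample is unknown and no counting interval or detection floor is given. TPM values are shares of a fixed total, so a large change in abundant transcripts shifts all others. An exact 0 can be a failed estimate, so such genes are described as listed at 0, with the value of each library.

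Isoform values were summed to 27655 genes by the locus identifier. Names, products and positions were taken from the TAIR10.1 annotation, in which 27445 of the genes (99.2%) had an entry. Coordinates are those of TAIR10.1 and were not combined with any from the deposited table. Reads from near-identical copies can be split between them by the quantification, so single members of such families are uncertain. No column of another sample was present (0).

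The comparison of genotypes used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), for the 19527 genes with a mean of at least 1 TPM over the 6 samples. The model held genotype only, with variances moderated by a mean-variance trend and robust estimation. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Fold changes are differences on the log2(TPM + 1) scale, sos2-2 minus wild type, and understate the change of genes near 1 TPM. A second count required an absolute log2 fold change of at least 1. Fold values given as ratios are ratios of mean TPM. Values after ± are standard deviations of 3 samples unless another error is named.

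A set of 34 gene lists with 530 entries was fixed from textbook knowledge before the data were examined, as were the tests, the rule for naming genes and most alternatives. The reference gave the listed name for the identifier of 483 entries. It gave no such name for the other 47, which were kept, and 0 entries were removed. Whether any of the 47 carries the name of a different gene is not settled here. The entry listed as PARP1 (AT2G31320) has the product name poly(ADP-ribose) polymerase 2. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. The same test with the correlation estimated per list, and fry, were run beside it. Counts of called members are given over all genes tested and, for comparison, adjusted over the list alone. Shares of signal from organelle and photosynthesis genes were compared by a two-sided exact permutation test, whose smallest p with 3 against 3 samples is 0.1.

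Named genes followed a fixed rule. It took SOS1, SOS2, SOS3, GL1 and the PLETHORA list, and the 10 largest rises and the 10 largest falls among called genes with a symbol, read as a main symbol in the reference that differs from the locus identifier, synonyms aside. Those 20 had to have groups that do not overlap and a mean of at least 17.2 TPM, the median of tested genes. For each list with 3 or more called members it took the 2 with the smallest p, otherwise 1. Any other gene named was chosen after its values were seen.

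The fit was tested on simulated data of 19527 genes with the spread of these samples. Of 50 genes changed by 1 on the log2 scale 58% were recovered. The share was 92% for a change of 2, 98% for a change of 3 and 8% for a change of 0.5. Of 19307 unchanged genes 3 were called. The simulated comparison was that of sos2-2 with wild type. The changed genes were drawn from those at about 5 TPM or more in wild type. Few genes were changed there, while 65.5% of tested genes were called in the data. The adjusted threshold depends on the share of changed genes, so these figures do not give the recovery or false calls of the real comparison.

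Alternatives left out each sample in turn, changed the filter (none, or a mean of 5 TPM) and the pseudocount (0.1 or 5), rescaled the samples (TMM-type factors or quantile normalization), tested transcripts on their own, weighted the samples, or added the replicate number as a factor. A test on counts was planned for a table of counts and was not run on TPM. Figures were drawn in Python 3.11.15.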

Results

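Transcript levels were measured in root tips of 6-day-old Arabidopsis seedlings held in 100 mM NaCl for 12 hours, in 3 samples of wild type and 3 of sos2-2. SOS2 is a protein kinase of the Salt Overly Sensitive pathway; with the calcium sensor SOS3 it activates SOS1, the plasma membrane exchanger that moves sodium out of cells. The series concerns the upkeep of root meristems on salt by PLETHORA factors, the AP2-type regulators of the root stem cell niche. All 6 samples were on salt, so the comparison shows how the genotypes differed under salt, and a genotype difference present without salt cannot be separated from it. Values are TPM, in which each sample sums to 1000000, and sequencing depth is unknown. Between 18812 and 19141 genes reached 1 TPM in a sample.

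The genotypes differed across much of the transcriptome. Of 19527 genes tested, 12780 (65.5%) were called, 6115 higher and 6665 lower in sos2-2 (limma, adjusted p under 0.05). A difference of at least 2-fold was called for 6452 genes, 3180 higher and 3272 lower. The 3 values of each genotype did not overlap for 14079 genes (72.1%), where chance gives 10%. The median log2 fold change of all tested genes was -0.05. The first principal component held 88.7% of the variance and separated the genotypes. Correlations across genes were 0.976 to 0.991 between wild-type samples, 0.954 to 0.982 between sos2-2 samples and 0.726 to 0.824 across genotypes. Replicate 2 of sos2-2 lay nearest to the wild-type mean, at a root mean square log2 distance of 1.15, against 1.43 for replicate 1 and 1.30 for replicate 3.

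**Figure D1:**
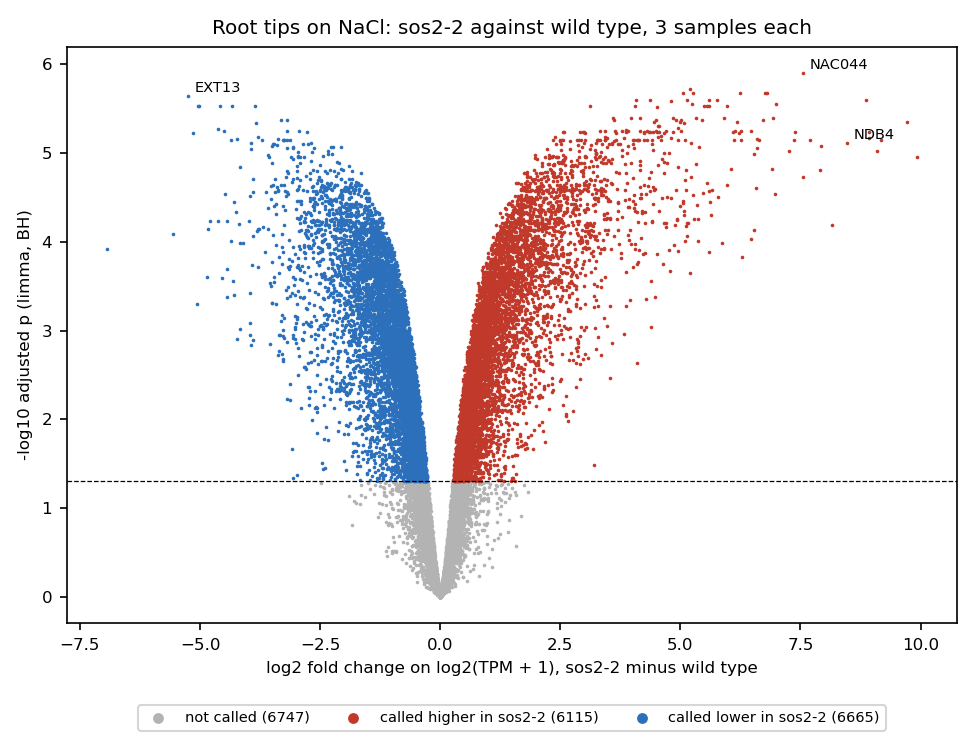
Each point is a gene; the x axis is the log2 fold change on log2(TPM + 1), sos2-2 minus wild type, and the y axis is -log10 of the adjusted p from limma, with 3 samples per genotype. The 6115 red points were called higher and the 6665 blue points lower in sos2-2; the dashed line marks an adjusted p of 0.05.

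Within the pathway that gives the mutant its name, SOS2 (AT5G35410, chromosome 5, 13634399 to 13638375 in TAIR10.1, 14 exons) rose from 5.41 ± 0.42 TPM in wild type to 15.5 ± 6.0 in sos2-2 (n = 3 each; log2 fold change 1.30, SE 0.25, adjusted p = 0.00289). The labels do not give the lesion of this allele, so the transcript level neither checks nor contradicts them. SOS3 rose 3.06-fold, from 23.0 ± 1.1 to 70.5 ± 0.4 TPM. SOS1 (chromosome 2, 457002 to 463408) was at 12.5 ± 0.6 and 12.9 ± 1.8 TPM, a difference smaller than the spread between replicates (adjusted p = 0.805). HKT1, a sodium transporter that withdraws sodium from the xylem, fell from 3.09 ± 1.10 to 0.335 ± 0.142 TPM (adjusted p = 0.000669). Of the 6 members of the SOS list 2 rose and 2 fell, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.867), whose median log2 fold change was -0.03 and mean 0.11. GL1 (AT3G27920), a trichome regulator named in the series' design, was listed at 0 in all 6 libraries. Whether the samples labelled wild type, or both genotypes, carry a gl1 allele is not given in the sources used here.

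PLETHORA genes moved apart. PLT1 (AT3G20840) stood at 6.05 ± 1.81 TPM in wild type and 5.95 ± 0.77 in sos2-2 (adjusted p = 0.983), and PLT2 (AT1G51190) at 6.20 ± 1.22 and 7.76 ± 1.64 (adjusted p = 0.241). PLT3 (AT5G10510, chromosome 5, 3315401 to 3320323, 9 exons) rose 6.15-fold, from 17.8 ± 2.6 to 109.3 ± 9.5 TPM (log2 fold change 2.56, SE 0.14, adjusted p = 1.27e-05). BBM fell from 5.00 ± 0.78 to 1.80 ± 0.38 TPM (adjusted p = 0.0012). PLT5 rose from 4.23 ± 0.67 to 6.76 ± 1.02 (adjusted p = 0.0194), a call lost without wild-type replicate 3 (adjusted p = 0.0854) or sos2-2 replicate 3 (0.0693). ANT was at 1.13 ± 0.32 and 0.968 ± 0.138 TPM and was not called. PLT7 (0.591 ± 0.180 and 0.543 ± 0.294 TPM) was below the filter, as was AIL1, which was listed at 0 in the 3 wild-type libraries and at 0.494, 0.904 and 0.791 in sos2-2. The list had 2 members higher, 1 lower and 3 not called of 6 tested, the same counts adjusted over the list alone (camera adjusted p = 0.551).

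**Figure D2:**
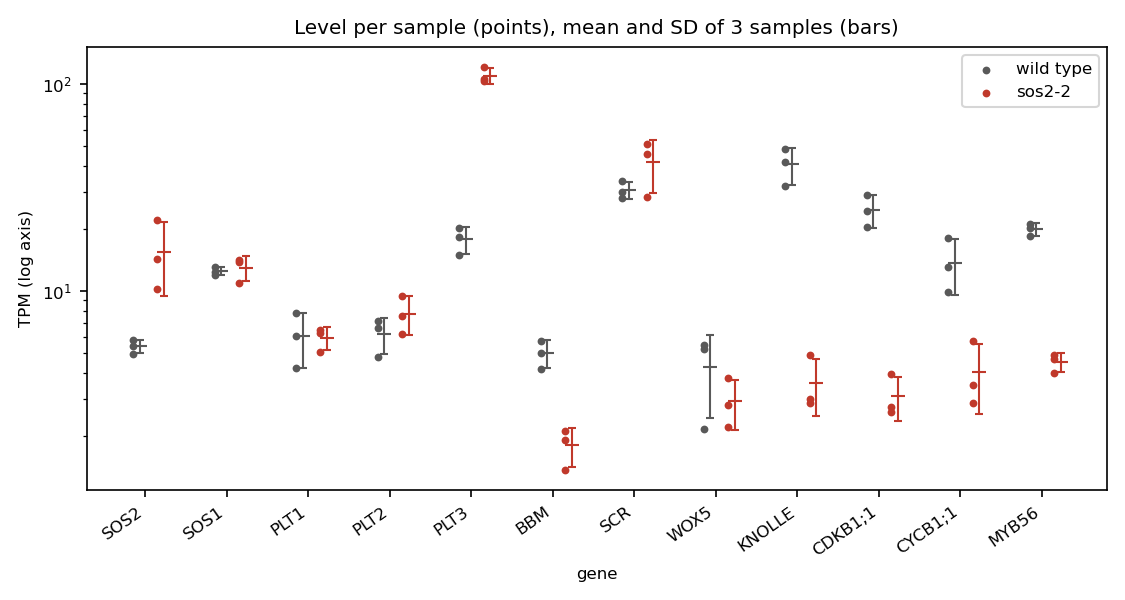
TPM on a log axis for 12 genes in wild type (grey) and sos2-2 (red); points are the 3 samples of each genotype and bars give the mean and SD. PLT3 rises from 17.8 to 109 TPM while PLT1 and PLT2 overlap between genotypes, and KNOLLE and CDKB1;1 are lower in all 3 sos2-2 samples. SCR, WOX5, CDKB1;1 and CYCB1;1 were chosen for the plot after their values were seen.

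Among other regulators of the stem cell niche, MYB56, also known as BRAVO, a repressor of quiescent centre division, fell from 19.9 ± 1.4 to 4.53 ± 0.47 TPM (adjusted p = 2.68e-05). TCP20 rose 2.12-fold (adjusted p = 0.000237). The list had 4 members higher, 2 lower and 4 not called, among the last SCR, SHR, JKD and WOX5, and was not called (camera adjusted p = 0.367). In the RGF list, of root meristem growth factor peptides and their receptors, 6 of 10 members fell and 2 rose. RGF3 fell 15.6-fold from 34.3 ± 2.2 TPM and RGF2 from 15.8 ± 1.6 to 0.832 ± 0.518 TPM, 18.9-fold, or 29.4-fold without sos2-2 replicate 2 (adjusted p = 7.88e-06 and 2.67e-05; list adjusted p = 0.148). Of 7 growth regulating factors and partners tested, 5 fell and 1 rose; GRF1 fell from 31.8 ± 4.9 to 7.39 ± 1.23 TPM and GRF6 from 6.30 ± 0.65 to 0.747 ± 0.066 (list adjusted p = 0.105).

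Genes of cell division were lower in sos2-2. All 26 members of the list for the G2 to M phase fell, also adjusted over the list alone, with a median log2 fold change of -2.02 (camera adjusted p = 2.56e-08). With an estimated correlation the list's adjusted p = 0.614. KNOLLE, the syntaxin of the cell plate, fell 11.3-fold from 40.8 ± 8.3 TPM, and the mitotic cyclin CYCB2;3 from 18.1 ± 3.1 to 1.63 ± 0.44 (adjusted p = 2.73e-05 and 2.63e-05). In the list for the G1 to S phase and DNA replication, 18 of 21 members fell and 0 rose (median -1.18, camera adjusted p = 0.000129; adjusted p = 0.614 with an estimated correlation). PCNA1 and PCNA2, the sliding clamp of replication, fell 5.89-fold and 4.46-fold, from 41.8 ± 6.5 and 44.0 ± 5.0 TPM. Of 17 replication-dependent histone genes 12 fell (median -0.77, camera adjusted p = 0.00101; adjusted p = 0.614 with an estimated correlation), HTR13 from 49.6 ± 10.6 to 6.68 ± 1.66 TPM and HTR2 from 245 ± 18 to 87.9 ± 10.4. Many histone genes are near-identical copies, so the value of each is uncertain. Inhibitors of cyclin-dependent kinases and endocycle genes went both ways, 7 higher and 5 lower of 17 (8 and 5 adjusted over the list alone; camera adjusted p = 0.734). SMR4 rose from 5.50 ± 0.89 to 47.4 ± 5.1 TPM, and KRP3 fell from 6.08 ± 0.96 to 1.67 ± 0.20. The DNA damage list had 6 members higher and 3 lower of 12, with 7 higher adjusted over the list alone (camera adjusted p = 0.215). In it GMI1 rose from 0.941 ± 0.128 to 8.91 ± 2.96 TPM and AGO2 from 7.09 ± 0.75 to 16.9 ± 1.2. Ribosome biogenesis genes were higher in 7 of 12 cases (5 adjusted over the list alone; median 0.41), PES from 96.8 ± 7.6 to 187 ± 16 TPM and WDR12 from 46.8 ± 7.6 to 76.4 ± 2.7. The list's adjusted p = 0.0402 by camera, and adjusted p = 0.775 with an estimated correlation. That call was also lost without wild-type replicate 2 (adjusted p = 0.0707) or sos2-2 replicate 2 (adjusted p = 0.0981).

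Genes of hormone responses were higher in sos2-2 for auxin and ethylene. In the auxin response list 17 of 23 members rose and 0 fell (median 1.55, camera adjusted p = 1.65e-05; adjusted p = 0.614 with an estimated correlation). LBD29, a lateral root factor, rose from 2.64 ± 0.23 to 155 ± 92 TPM (58.6-fold, or 38.7-fold without sos2-2 replicate 1) and ARF19, an activating auxin response factor, from 9.54 ± 0.91 to 52.7 ± 6.7 (adjusted p = 2.97e-05 and 1.64e-05). In the ethylene list 14 of 19 members rose and 3 fell (median 2.57, camera adjusted p = 0.000586; adjusted p = 0.614 with an estimated correlation). ACS7, an enzyme that makes the ethylene precursor, rose 54.8-fold, from 7.68 ± 0.69 to 421 ± 81 TPM. ERF105 was listed at 0 in the 3 wild-type libraries and at 112, 48.1 and 80.6 TPM in sos2-2. Auxin transport and synthesis had 9 members higher and 3 lower of 18 (adjusted p = 0.215), with PID up from 8.98 ± 1.12 to 56.6 ± 8.5 TPM and PIN3 from 31.8 ± 4.4 to 106 ± 13. Cytokinin genes had 9 higher and 4 lower of 20 (adjusted p = 0.293); IPT5, which makes cytokinin, rose 3.02-fold, and AHP6, an inhibitor of cytokinin signalling, stood at 3.19, 2.23 and 2.89 TPM in wild type and at 0.357, 0 and 0.143 in sos2-2. Jasmonate genes had 9 higher and 4 lower of 17 (adjusted p = 0.155), with JAZ6 up 2.39-fold and LOX4 up 7.11-fold. For these 5 lists the counts adjusted over the list alone were the same.

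Stress lists divided. Pathogen defence genes rose in 15 of 16 cases, with 0 lower (median 2.02, camera adjusted p = 6.88e-06; adjusted p = 0.614 with an estimated correlation). Its transcription factors WRKY70 and WRKY18 rose from 8.37 ± 0.56 to 174 ± 63 TPM and from 47.0 ± 1.8 to 237 ± 44. The reactive oxygen list had 10 higher and 7 lower of 23 (adjusted p = 0.318). AOX1A, the alternative oxidase of mitochondria, rose 50.1-fold, from 33.4 ± 4.4 to 1674 ± 367 TPM, and the kinase OXI1 27.3-fold, from 30.2 ± 1.0 to 825 ± 211. In the endoplasmic reticulum unfolded protein list 8 of 11 members fell and 3 rose (median -1.58, camera adjusted p = 0.046; adjusted p = 0.614 with an estimated correlation). The members that fell include the chaperones CNX1, from 301 ± 12 to 61.7 ± 4.8 TPM, and HSP90-7, from 309 ± 11 to 90.2 ± 7.4. Among those that rose was BZIP60, an activator of this response, from 59.7 ± 7.3 to 823 ± 294 TPM, which was chosen after its values were seen. The call of this list was lost without wild-type replicate 2 (adjusted p = 0.0549), sos2-2 replicate 1 (0.0551) or sos2-2 replicate 2 (0.0876).

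Abscisic acid and osmotic stress genes had 5 members higher and 13 lower of 28 (adjusted p = 0.155). LEA14 fell from 165 ± 42 to 22.6 ± 8.1 TPM and DREB2A rose from 41.1 ± 3.8 to 309 ± 118. Hypoxia genes had 2 higher and 8 lower of 13 (adjusted p = 0.274); LBD41 fell 15.6-fold and HRE2 rose 94.8-fold. Wild-type replicate 1 stood apart in these lists, with ADH1, alcohol dehydrogenase, at 7.89 TPM against 106 and 73.3 in the other wild-type samples, a gene chosen after its values were seen. Without that library camera called both lists lower at the preset correlation only (adjusted p = 0.00358 and 0.00291; adjusted p = 0.616 for each with an estimated correlation). In the ion transport list 4 members rose and 9 fell of 20 (adjusted p = 0.318), with CAX1 up 3.61-fold and the potassium transporter HAK5 down from 8.52 ± 2.87 to 0.440 ± 0.199 TPM. Autophagy genes had 6 higher and 3 lower of 13 (adjusted p = 0.318), including ATG8E, up 8.54-fold, and NBR1, up 3.70-fold. Heat shock genes had 4 higher and 5 lower of 13 (adjusted p = 0.954), with HSFA7A up 4.59-fold and HSP23.6 up 13.9-fold (21.8-fold without wild-type replicate 3). Their median log2 fold change was -0.29 and their mean 0.13, with camera in the lower direction. In the iron list FIT rose and NAS4 fell, 1 each of 7 (adjusted p = 0.954), with a median of 0.22, a mean of -0.26 and camera in the higher direction. Among the 7 developmental cell death genes tested 6 fell and 0 rose (camera adjusted p = 0.105). RNS3 fell from 44.4 ± 2.1 to 21.8 ± 2.2 TPM and PASPA3 from 19.3 ± 4.0 to 9.54 ± 1.47. Adjusted over the list alone, the counts of these lists, and of the defence, reactive oxygen and unfolded protein lists, were the same.

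Markers of cell types differed in direction. Of 18 root hair markers 12 fell and 2 rose (13 and 3 adjusted over the list alone; median -1.28, camera adjusted p = 0.00287; adjusted p = 0.614 with an estimated correlation). PRP3 fell from 1157 ± 184 to 137 ± 14 TPM and RHS18 from 210.1 ± 30.7 (log2 fold change -2.76). Of 16 markers of endodermis and suberin 13 fell and 1 rose (median -1.72, camera adjusted p = 0.0402; adjusted p = 0.775 with an estimated correlation). CASP2, a protein of the Casparian strip, fell from 131 ± 21 to 11.1 ± 11.7 TPM (11.7-fold, or 29.2-fold without sos2-2 replicate 2) and FAR5 from 80.9 ± 18.6 to 19.6 ± 3.1. This call was lost without wild-type replicate 2 (adjusted p = 0.0707). Phloem markers had 4 higher and 0 lower of 7 (adjusted p = 0.105), with BRX up from 1.74 ± 0.21 to 30.4 ± 16.3 TPM and APL up 3.26-fold. Xylem and secondary wall markers had 2 higher and 8 lower of 13 (adjusted p = 0.318), with VND6 up 6.58-fold and ACL5 down 8.77-fold. Root cap markers had 2 higher and 2 lower of 6 (adjusted p = 0.954), with SMB up 1.84-fold and BRN2 up 1.66-fold; their median was -0.00187 and their mean -0.12, with camera in the higher direction. Wall loosening and cellulose genes had 6 higher and 3 lower of 17, with 5 higher adjusted over the list alone (adjusted p = 0.404); XTH18 rose 7.28-fold. Photosynthesis genes had 2 higher and 7 lower of 17, with 6 lower adjusted over the list alone (adjusted p = 0.318), PSBO2 from 10.5 ± 3.0 to 1.86 ± 0.79 TPM and LHCB3 1.88-fold, to 5.85 ± 0.47 TPM. Among 9 genes often used as references 4 fell and 1 rose (adjusted p = 0.318), UBC21 from 55.8 ± 1.4 to 30.4 ± 3.6 TPM and SAND from 29.5 ± 2.3 to 19.1 ± 0.1. In all, camera called 10 of the 34 lists, 4 higher and 6 lower, and with an estimated correlation called 0, with 2 at an unadjusted p under 0.05. Fry called 21 for a shift in 1 direction.

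**Figure D3:**
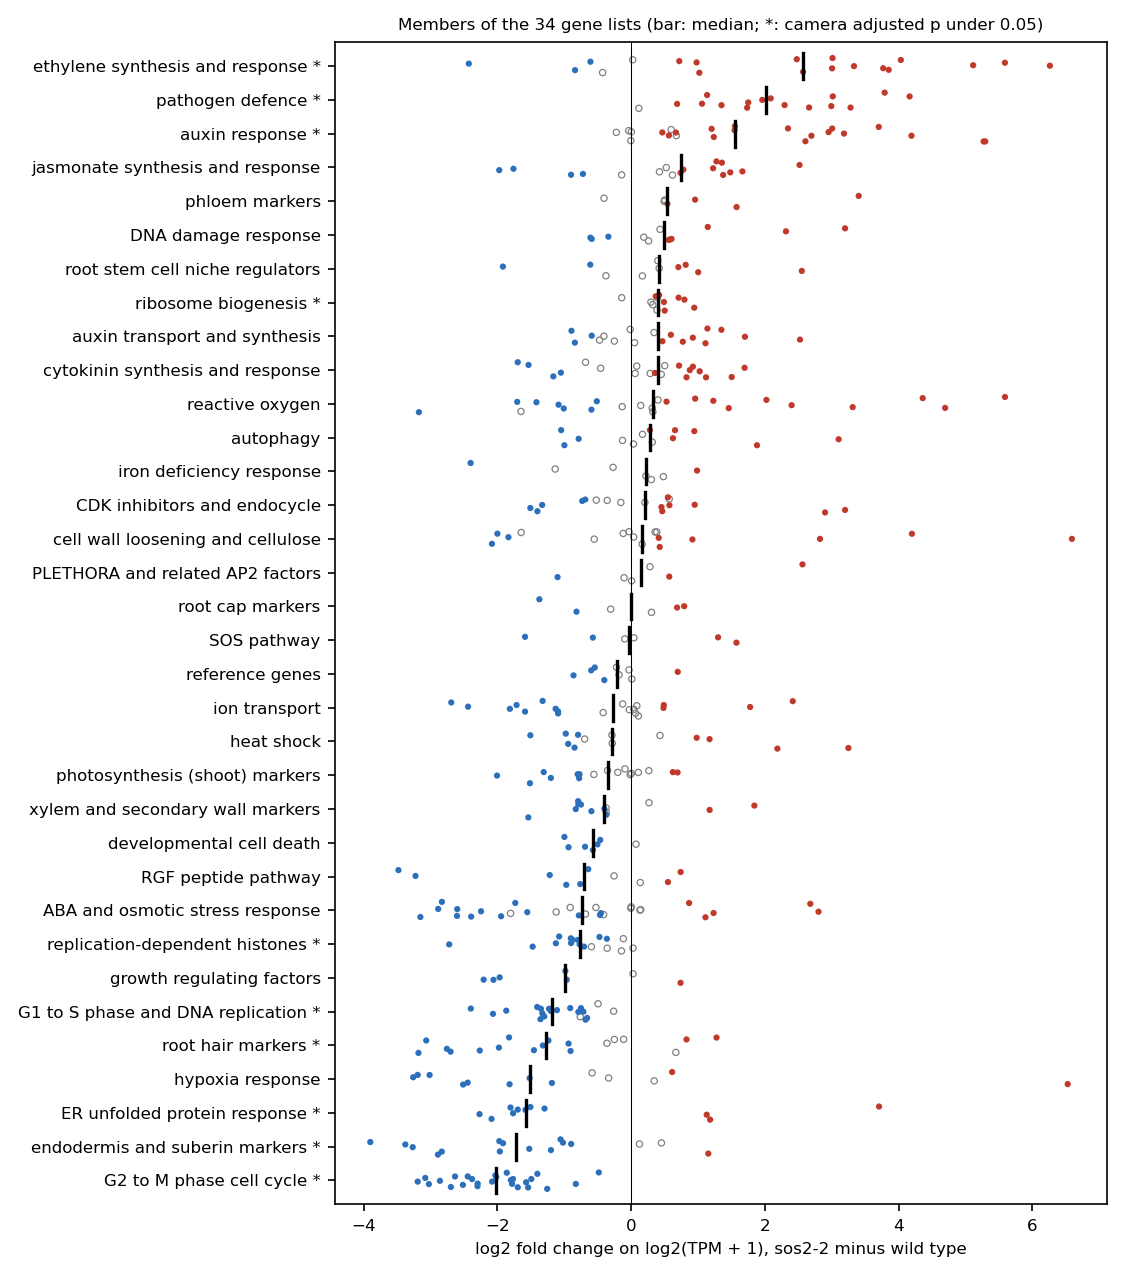
Log2 fold change on log2(TPM + 1), sos2-2 minus wild type, of each tested member of the 34 gene lists; red and blue points were called higher and lower, open points were not called, and black bars are medians. The lists are ordered by median, from -2.02 for the G2 to M phase to 2.57 for ethylene, and an asterisk marks the 10 called by camera with a preset correlation.

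The largest rises among abundant genes with a symbol included NDB4, an NAD(P)H dehydrogenase of mitochondria, from 0.491 ± 0.371 TPM in wild type to 569.7 ± 314.5 in sos2-2 (log2 fold change 8.47, SE 0.38, adjusted p = 7.66e-06), a ratio of 1162, or 1899 without wild-type replicate 3. NAC044, a NAC transcription factor, rose from 0.777 ± 0.078 to 337 ± 57 TPM (log2 fold change 7.56, SE 0.14, adjusted p = 1.26e-06). CRF6, a cytokinin response factor, rose 136-fold, the P450 enzyme CYP81D8 123-fold, the sulfotransferase SOT12 103-fold and the wall enzyme TCH4 102-fold. DFD rose 201-fold and sks8 997-fold from wild-type means of 0.610 and 0.132 TPM; sks8 stood at 267, 41.1 and 87.3 TPM in sos2-2, a rise of 486-fold without replicate 1. DOGT1, a glucosyltransferase, stood at 0.068, 0 and 0.211 TPM in wild type and at 201, 55.3 and 99.4 in sos2-2. The hypoxia factor HRE2 completed the 10 largest rises among genes whose main symbol in the reference differs from the locus identifier. Genes left out by that limit include ERF105 and AT5G09570, with log2 fold changes of 6.26 and 6.28, above that of DFD (6.21), the smallest of the 10.

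The largest falls among abundant genes with a main symbol were led by cell wall extensins. Genes left out by that limit include AT5G06630 and AT5G05960, with log2 fold changes of -5.14 and -4.34. Both are larger falls than that of GSTF9 (-3.92), the smallest of the 10. EXT13 fell from 1210 ± 129 to 30.8 ± 4.1 TPM (log2 fold change -5.25, SE 0.14, adjusted p = 2.27e-06), EXT10 from 397 ± 183 to 13.1 ± 5.3 and EXT6 from 434 ± 86 to 24.6 ± 10.9. Extensin genes share repeats, so the split of reads between them is uncertain. BCAT4 and IMS2, enzymes linked to glucosinolate synthesis from methionine, fell 51.1-fold and 22.2-fold, and the methionine synthase MS2 fell 19.1-fold. CYP705A5 fell 30.3-fold, the peptide gene CLE5 14.3-fold and the glutathione transferase GSTF9 13.5-fold. Without sos2-2 replicate 2 the falls were 51.8-fold for CYP705A5, 24.5-fold for CLE5 and 34.4-fold for IMS2. ELIP2 fell from 40.4 ± 35.4 to 0.772 ± 0.447 TPM, with wild-type values of 79.5, 10.5 and 31.1, a fall of 52.3-fold that was about 27.0-fold without wild-type replicate 1.

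Shares of signal by origin were compared by a permutation test that could call none of them, since its smallest possible p with 3 against 3 samples is 0.1. Chloroplast genes gave 0.00695% ± 0.00306 of signal in wild type and 0.00823% ± 0.00395 in sos2-2 (exact permutation p = 0.8, two-sided). Mitochondrial genes gave 0.0182% ± 0.0065 and 0.0167% ± 0.0221 (exact permutation p = 1). The mitochondrial share in sos2-2 was 0.00487%, 0.0422% and 0.0031% in replicates 1, 2 and 3, so its mean rested on replicate 2. Without that sample the difference, sos2-2 minus wild type, went from -0.00142 to -0.0142 percent. Photosynthesis genes gave 0.0363% ± 0.0052 and 0.0303% ± 0.0011, every sos2-2 value below every wild-type value (exact permutation p = 0.1, the smallest possible). A single short gene model, AT2G01021 (chromosome 2, 6571 to 6672), took the largest share of any gene in the 3 wild-type samples and in sos2-2 replicate 2, but not in the other sos2-2 samples. It lies downstream of the ribosomal RNA genes AT2G01010 (3706 to 5513) and AT2G01020 (5782 to 5945). It held 5.55%, 1.79% and 1.44% of signal in wild type and 0.439%, 3.66% and 0.191% in sos2-2 (exact permutation p = 0.5).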

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

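The alternatives that leave out AT2G01021, leave out both libraries that stand apart (wild-type replicate 1 and sos2-2 replicate 2), estimate sample weights gene by gene, or estimate the correlation without wild-type replicate 1, and the reading of the splits, were chosen after seeing the data; the others were fixed before. The count of 12780 genes stayed within 1.5 times under every alternative run. Leaving out 1 sample gave 10658 to 12898 genes, and 6067 to 7056 at 2-fold; 7 to 12 lists were called. Without both libraries 12079 genes were called, 11391 of them shared with the same direction. Without AT2G01021 the count was 12772. The planned sample weights gave 17681 genes, but their estimate stopped before convergence, with weights of 0.162 to 20.6, so it is not relied on; the gene-by-gene estimate gave 14989. The 2-fold count fell to 4248 with a pseudocount of 5, which shrinks folds by construction. Lists called by camera numbered 0 with an estimated correlation (2 at an unadjusted p under 0.05), also 0 without wild-type replicate 1 (1 unadjusted), and 21 with fry, which does not compare a list with other genes. Apart from left-out single samples, ribosome biogenesis lost its call with a mean of 5 TPM (adjusted p = 0.0546), without AT2G01021 (0.0571) and with gene-by-gene weights (0.0772). The unfolded protein list lost it with quantile normalization (0.0632), without AT2G01021 (0.0571), without both libraries (0.0689), with the planned weights (0.15) and with gene-by-gene weights (0.085). Endodermis lost it with fry (0.0736). At the preset correlation camera gained calls for jasmonate with a mean of 5 TPM (0.0358) and developmental cell death with no filter (0.0471). It also gained calls for abscisic acid and hypoxia without both libraries (0.00331 and 0.00599). PLT2 (0.0186) and ANT (0.00213) were called with the planned, unconverged weights only. The share of higher calls, in either count, stayed between 45.7% and 52.8%. The edgeR test planned for counts was not run, as the table holds TPM and not counts, and fry's mixed test called all 34 lists.

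Of 87 called named genes 85 kept direction and call under every alternative run; PLT5 and TCP20 lost the call in some, TCP20 for its most abundant transcript alone (adjusted p = 0.132). Reversals concerned results that were not called. SOS1 moved between -0.0204 and 0.15 when a sample was left out, to -0.0175 with quantile normalization and to -0.0271 without both libraries. PLT1 moved between -0.191 and 0.188, to -0.00254 with a pseudocount of 5 and to -0.0135 without AT2G01021. ANT moved to 0.0129 with quantile normalization. The adjusted p of the heat shock list ran from 0.534 to 0.973 with a sample left out, 0.894 with a mean of 5 TPM, 0.995 with a pseudocount of 5 and 0.761 with fry; that of the iron list ran from 0.657 to 0.973, and 0.403 with fry. For these reversals the cause was not tested. With a sample left out the differences in signal share moved by less than 1 pooled SD. Depth, unknown here, limits low genes.

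Replicate numbers are shared between genotypes in the labels, but deviations of same-numbered samples correlated at 0.177, 0.0505 and 0.0575, and wild-type replicate 2 correlated best with sos2-2 replicate 3 (0.182), so the numbers were not taken to pair samples. With the replicate block 12547 genes were called, 6504 at 2-fold, and 8 lists; ribosome biogenesis (adjusted p = 0.0535) and the unfolded protein list (0.0711) were not called with it, and no other list or named gene changed its call.

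The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 12780 genes (6452 at 2-fold) and 1 of 10 splits, the real one, reached this. The highest other split called 0 by limma, with 231 at an unadjusted p under 0.05. Every other split mixed the genotypes, so the genotype difference entered the spread within groups. Their low counts were close to given beforehand and are no reference for chance.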

Other observations

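The product families, the added meristem comparison and the use of the DNA damage list were chosen after results were seen; the tests on NAC085, on sos2-2 replicate 2 and on the 12 mitochondrial stress genes were set before those values were looked at. Genes grouped by the product name in the reference gave 20 families, of which camera called 8, 3 higher and 5 lower, with 12 not called. With an estimated correlation 0 were called, 1 at an unadjusted p under 0.05. WRKY transcription factors rose in 37 of 48 cases and fell in 3 (median log2 fold change 1.74, adjusted p = 6.35e-09), among them WRKY48, from 7.76 ± 0.33 to 192 ± 47 TPM, and WRKY28, from 3.16 ± 0.95 to 70.4 ± 8.3. NAC factors rose in 35 of 58 cases and fell in 7 (median 0.85, adjusted p = 3.45e-05), NAC048 from 13.9 ± 2.2 to 245 ± 3.4 TPM. C2H2 zinc finger genes had 25 higher and 14 lower of 53 (adjusted p = 0.0409), with AT3G46080 up to 675 ± 172 TPM (log2 fold change 6.47).

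Proteasome subunits fell in 27 of 36 cases and rose in 1 (median -0.64, adjusted p = 2.04e-05), PBD2 from 99.6 ± 2.7 to 42.8 ± 3.8 TPM and PAG1 from 232 ± 11 to 100.2 ± 10.9. Kinesins fell in 21 of 27 cases and rose in 1 (median -1.51, adjusted p = 9.16e-05), among them MRH2, a kinesin of root hairs, from 11.1 ± 0.9 to 2.60 ± 0.46 TPM. Aquaporins fell in 19 of 26 cases and rose in 4 (median -0.87, adjusted p = 0.0164). The vacuolar TIP2;2 fell from 431 ± 58 to 35.7 ± 8.5 TPM while NIP5;1, which carries boric acid, rose from 90.7 ± 2.1 to 472 ± 99. Lipid transfer proteins fell in 30 of 52 cases and rose in 10 (median -1.25, adjusted p = 0.0106), and extensins fell in 13 of 22 and rose in 3 (median -1.32, adjusted p = 0.0409). The adjusted p = 0.57 for WRKY, 0.586 for NAC and 0.663 for each of the other 6 families with an estimated correlation.

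The rise of NDB4 and AOX1A, both of the alternative respiratory pathway, led to the hypothesis of a mitochondrial stress response in sos2-2 root tips on salt. It was tested on 12 other genes known to respond to mitochondrial dysfunction. NDA1, NDA2, NDB2 and AOX1D among them are of the same pathway as NDB4 and AOX1A. Their rise is therefore not independent of the observation that led to the hypothesis. All 12 were called higher, with a median log2 fold change of 5.42 (camera p = 1.15e-08, and p = 0.0607 with an estimated correlation), including OM66, from 33.0 ± 4.8 to 1511 ± 345 TPM, and ANAC013, a regulator of this response, from 5.53 ± 1.21 to 407 ± 77. That median stood at percentile 100 of 10000 random lists matched on mean expression, whose 99th percentile was 0.80, so genes at this abundance did not rise in general. With a median of -0.05 over all tested genes, that outcome was close to given beforehand. The random genes were drawn singly, while the 12 genes had an estimated correlation of 0.4, so the percentile is no measure of support for the hypothesis. The data are consistent with the hypothesis, but several of these genes also answer oxidative and chemical stress, which was not tested apart, and no untreated samples show whether salt is needed.

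The fall of all 26 G2 to M phase genes could reflect a smaller share of meristem RNA. The 33 tested genes of the niche, PLETHORA, RGF and growth regulating factor lists had a median of -0.11 (SD 1.37) against -2.02, but the lists differ. The 16 niche and PLETHORA genes had a median of 0.34 (SD 1.14), with 6 higher, 3 lower and 7 not called. They did not fall together, as an even loss of meristem RNA that includes them would predict. Whether they are confined to the meristem was not tested, so they do not decide against such a loss. The 17 others had a median of -0.96 (SD 1.28), within their SD of -2.02, and do not argue against such a loss. A smaller share of meristem RNA and fewer dividing cells outside the niche therefore stay open. So do, untested, a direct effect of the genotype and one of the mutant's salt load. NAC044 and its relative NAC085 are known to hold back the G2 to M phase. NAC085 was listed at 0, 0.042 and 0 TPM in wild type and 5.50, 1.54 and 2.59 in sos2-2 (log2 fold change 1.94, adjusted p = 0.00146). The hypothesis of repression through these factors predicts this rise. But 35 of 58 NAC factors and 6115 of 19527 tested genes were called higher, so the prediction could pass whatever the cause and does not decide it. Whether DNA damage lies upstream cannot be told apart here. Camera did not call that list (adjusted p = 0.215), and its members went both ways. Fry, which does not compare a list with other genes, called it higher (adjusted p = 0.0036).

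Replicate 2 of sos2-2 lay nearest to wild type, and an admixture of wild-type RNA might explain it. Genes differing between wild type and the other sos2-2 replicates imply a wild-type share of 0.382 from the 1235 that rose and 0.0765 from the 940 that fell, a difference of -0.306 (95% bootstrap interval over genes, which are not independent, -0.317 to -0.288), which an admixture alone would not give. The same measure gave 0.242 for replicate 1 and -0.00487 for replicate 3, so it also departs from 0 in a sample that does not lie near wild type, and a small admixture stays open. A smaller response in proportion would reach the same fraction of the log2 change in both sets, and these were 0.82 and 0.795, a difference of -0.0257 (95% interval -0.0444 to -0.011); with differences of -0.0039 for replicate 1 and -0.018 for replicate 3 this does not single out replicate 2, though their fractions were higher, 1.10 to 1.11 and 1.00 to 1.02. Without AT2G01021 replicate 2 was still the nearest, at a distance of 1.154, against 1.434 and 1.304, so the share of that gene is argued against. The smaller response in proportion restates that replicate 2 lay nearer to wild type, and no biological explanation was tested.

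Wild-type replicate 1 held IRT1, an iron transporter, at 40.9 TPM, against 2.39 and 2.68 in the other wild-type samples and 3.94, 1.81 and 2.56 in sos2-2. SMR5, an inhibitor of cyclin-dependent kinases, was listed at 0 there, at 22.3 and 10.9 TPM in the other wild-type samples and at 102, 34.9 and 56.6 in sos2-2.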
